A study of Solanum lycopersicum with 8 samples.

How the data were processed

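RNA was measured in 8 libraries of embryos of the tomato cultivar Micro-Tom, 4 of wild type and 4 of the slnrpd1 mutant, collected 21 days after flowering. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with an NEBNext Ultra II RNA kit, which does not mark strand. The labels give a replicate number for each library and do not say whether replicates are separate plants, separate pools of embryos or repeated libraries of 1 extract. The chi-square per degree of freedom between libraries of a group was 2.98 to 53.0, above the value near 1 of resequenced libraries.

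The submitters' processing notes name Trim Galore 0.6.7, HISAT2 2.2.1, featureCounts 2.0.1 and DESeq2 1.36.0, with no role, order or genome build. The gene table gives the deposited signal per gene and library as read counts divided by 1 size factor per library, which was worked out from the values. Each value is a whole multiple of the library's smallest value, and after division 100% of the values lay within 0.05 of a whole number, which gave back the reads. The same table gives the authors' log2 fold change and the authors' p-value and adjusted p-value per gene, used only for the comparison of calls, with 37 genes listed without a p. The element table gives the deposited signal of counted regions in the same unit and with the same size factors, the authors' log2 fold change and the authors' p-values, on SL4.0 coordinates, per the file headers. It holds only elements with an adjusted p under 0.05 and an absolute log2 fold change over 1 (largest adjusted p 0.0234, smallest absolute log2 1.01). Up to 94 elements share 1 counted region, so values were taken once per region.

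Gene identifiers and descriptions are those the gene table pairs. No identifier matched the given RefSeq gene table, and gene coordinates were not used here, so the planned test of changed genes near listed elements was not run. The mutated gene itself was not analysed here. Reads of near-identical copies, such as histones, chitinases and vicilins, and of overlapping or antisense genes could be assigned to the wrong member, and values of single members are uncertain to that extent.

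The planned main test was edgeR's quasi-likelihood test on counts, with limma where the table holds normalized counts. The table held normalized counts, so limma-trend (eBayes with trend and robust) was run on log2(normalized count + 1) for genes with a value of at least 1 in at least 4 libraries, with genotype as the only factor and Benjamini-Hochberg adjustment at 0.05. A change of at least 2-fold was an absolute fitted log2 change of at least 1. Element regions, planned for edgeR on counts, were fitted together with the genes in limma for the same reason and adjusted over the regions. The libraries held 27.2 to 31.5 M reads over genes. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0 and matplotlib 3.10.9 were used.

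23 gene lists were fixed by words in the gene descriptions and a few identifiers, among them 3 lists of markers of other tissues (endosperm, seed coat, fruit flesh and ripening). The 22 lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists. With an estimated correlation 0 lists passed an adjusted p of 0.05 and 5 an unadjusted one, and fry, which tests whether the genes of a list move one way without comparing them with other genes, called 18. The estimate was 0.0055 for ethylene, 0.0099 for cell wall and 0.0077 for MADS-box genes, under the preset value, and larger for the other called lists. A larger correlation is therefore not why these lists lost their calls. That setting also takes its degrees of freedom from the libraries and not from the genes, which lowers its power. Some descriptions take in genes that do not belong: an immunoglobulin in the storage protein list, a ribosomal export protein in the ribosomal list, and methyltransferases counted in both methylation lists. The named genes follow a rule: every tested member of the RNA-directed DNA methylation list; the 10 largest rises and 10 largest falls among genes past the threshold with at least 5 CPM in the higher group, no overlap of the groups and a known description; and per list up to 4 members with the smallest adjusted p among those past the threshold, or, where there are none, the 2 with the highest mean. Of the 133 genes this gave, 119 passed the test, and not all are described singly.

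For genes without a WT read the fold is a lower bound against 3 reads over the WT group, and for 1 to 3 reads the ratio is given with its 95% exact counting interval. In a single library 3 reads stand for 0.0952 to 0.11 CPM. Single values were compared with two-sided exact permutation tests.

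The scripts were tested on simulated counts for this comparison, with 22518 genes of which 200.0 were changed. Of 50 genes changed at each size, 34% were recovered at 1.5-fold, 74% at 2-fold, 94% at 4-fold and 92% at 8-fold, and 9 of 22318 unchanged genes were called. The changed genes were drawn only from genes with a mean normalized count of at least 20, and few genes were changed. These rates therefore do not cover genes near silence in WT, or data in which a large share of genes changes. Of simulated lists the shifted list was called and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other, whereas the estimated correlation of the real lists reached 0.345. The simulation therefore does not show how often camera calls unchanged lists whose genes move together.

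The tests of genes and lists, the lists and the naming rule were fixed before the data were examined, and the tests of traces in WT libraries and of gene families were not. Alternatives planned beforehand were a pseudocount of 0.1, no filter, an adjusted p of 0.01, a replicate block, leaving out each library, edgeR and DESeq2 on the recovered reads with other scalings and filters, other list tests, and other library sizes and limits for elements. Added after the data had been seen were edgeR with TMM, limma with TMM, upper-quartile and library-total scaling, leaving out WT 1 and WT 4, edgeR for the elements, and the repeated filter when a library is left out. edgeR with TMM on the recovered reads tested 19603 genes and called 10059, of which 9801 were also called by limma, all in the same direction.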

Results

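Tomato (*Solanum lycopersicum*, cultivar Micro-Tom) embryos collected 21 days after flowering were profiled by RNA sequencing. The 8 libraries form 2 groups, wild type (WT, 4 libraries) and slnrpd1 mutant (nrpd1, 4 libraries). NRPD1 is the largest subunit of RNA polymerase IV, the plant-specific polymerase whose transcripts feed the small RNAs of RNA-directed DNA methylation. The libraries held 31.5, 31.0, 28.9 and 27.2 M reads over genes in WT 1 to WT 4, and 28.0, 31.3, 30.9 and 27.5 M in nrpd1 1 to nrpd1 4. Levels below are normalized read counts, as the mean ± SD over 4 libraries of a group, and changes are log2 differences of nrpd1 minus WT on the log2(normalized count + 1) scale, which understates the change of low transcripts. A fold against a group with no read uses a floor of 3 reads over the group, and floors and intervals cover counting error only. The transcript of the mutated gene was not analysed here, so the genotype labels were not checked against it.

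The comparison asks which transcripts differ between nrpd1 and WT embryos. Any other difference between the groups, such as in growth, harvest or embryo stage, cannot be told apart from the genotype here. The replicate unit is not stated, so the p-values measure spread between libraries, which may not be spread between plants. Among the largest rises were transcripts of single defence proteins that were low or absent in WT embryos. Chitinase Z15140 (Solyc10g055810.2), an enzyme that degrades fungal cell walls, rose from 24.0 ± 2.08 to 8044 ± 2950 (log2 change 8.27, SE 0.21, limma adjusted p = 1.08e-08). Acidic endochitinase (Solyc05g050130.4) stood at 75.9 ± 86.6 in WT, with 146 and 156 in WT 1 and WT 4 and 0.982 and 1.05 in WT 2 and WT 3, and at 30562 ± 16649 in nrpd1 (limma adjusted p = 0.00326). Pathogenesis related protein P23 (Solyc08g080650.3) had no read in any WT library and a level of 1539 ± 991 in nrpd1, at least 2055-fold higher. In the other direction, 1-aminocyclopropane-1-carboxylate oxidase1 (Solyc06g073580.4), of the family that makes ethylene, fell from 548 ± 173 to 3.34 ± 4.80 (log2 change -7.54, SE 0.63, limma adjusted p = 7.32e-06).

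The other large rises held several proteinase inhibitors, proteins that block the digestive enzymes of herbivores. Proteinase inhibitor 1 PPI3A2 (Solyc09g083435.1) was at least 1822-fold higher in nrpd1, cysteine proteinase inhibitor (Solyc06g073587.1) at least 1297-fold and pathogenesis-related protein 1 (Solyc09g007010.1) at least 1141-fold, all without a read in WT. Transcripts with 1 or 2 reads over the WT group were NIMIN2c protein (Solyc03g119590.1), with a ratio of 5837 and a 95% counting interval of 1047 to 230600, threonine deaminase (Solyc09g008670.3), with a ratio of 4064 and an interval of 1125 to 33560, proteinase inhibitor type-2 (Solyc03g098795.1), with a ratio of 3726 and an interval of 1031 to 30770, and thaumatin-like protein (Solyc08g080590.3), with a ratio of 2458 and an interval of 680 to 20300. A 2-oxoglutarate and Fe(II)-dependent oxygenase (Solyc04g009860.4) rose from 0.96 ± 1.92 to 1244 ± 612. The other large falls included terpene synthase 18 (Solyc08g005720.4), from 435 ± 77.5 to 3.59 ± 6.51, a cytochrome P450 (Solyc06g073570.4), from 304 ± 54.2 to 4.62 ± 3.42, and gibberellin 20-oxidase-1 (Solyc03g006880.3), an enzyme of gibberellin synthesis, from 237 ± 24.7 to 20.2 ± 19.9. Another 2-oxoglutarate and Fe(II)-dependent oxygenase (Solyc01g006610.2), abundant in WT at 57434 ± 3829, stood at 6632 ± 5499 in nrpd1 (limma adjusted p = 0.0116), a call lost when WT 1 and WT 4 were left out (adjusted p = 0.0505; 0.000259 to 0.0505 over the alternatives). An ethylene insensitive 3-like protein (Solyc05g051875.1) had levels of 1575 ± 202 and 245 ± 312 (limma adjusted p = 0.0213). This call was lost in 6 of 29 alternatives, with a range of 0.00242 to 0.0795 over the alternatives. Among them were leaving out WT 4 (adjusted p = 0.0525) or WT 1 and WT 4 (adjusted p = 0.0795), a replicate block (adjusted p = 0.0625) and edgeR without a count filter (adjusted p = 0.0647).

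**Figure D1:**
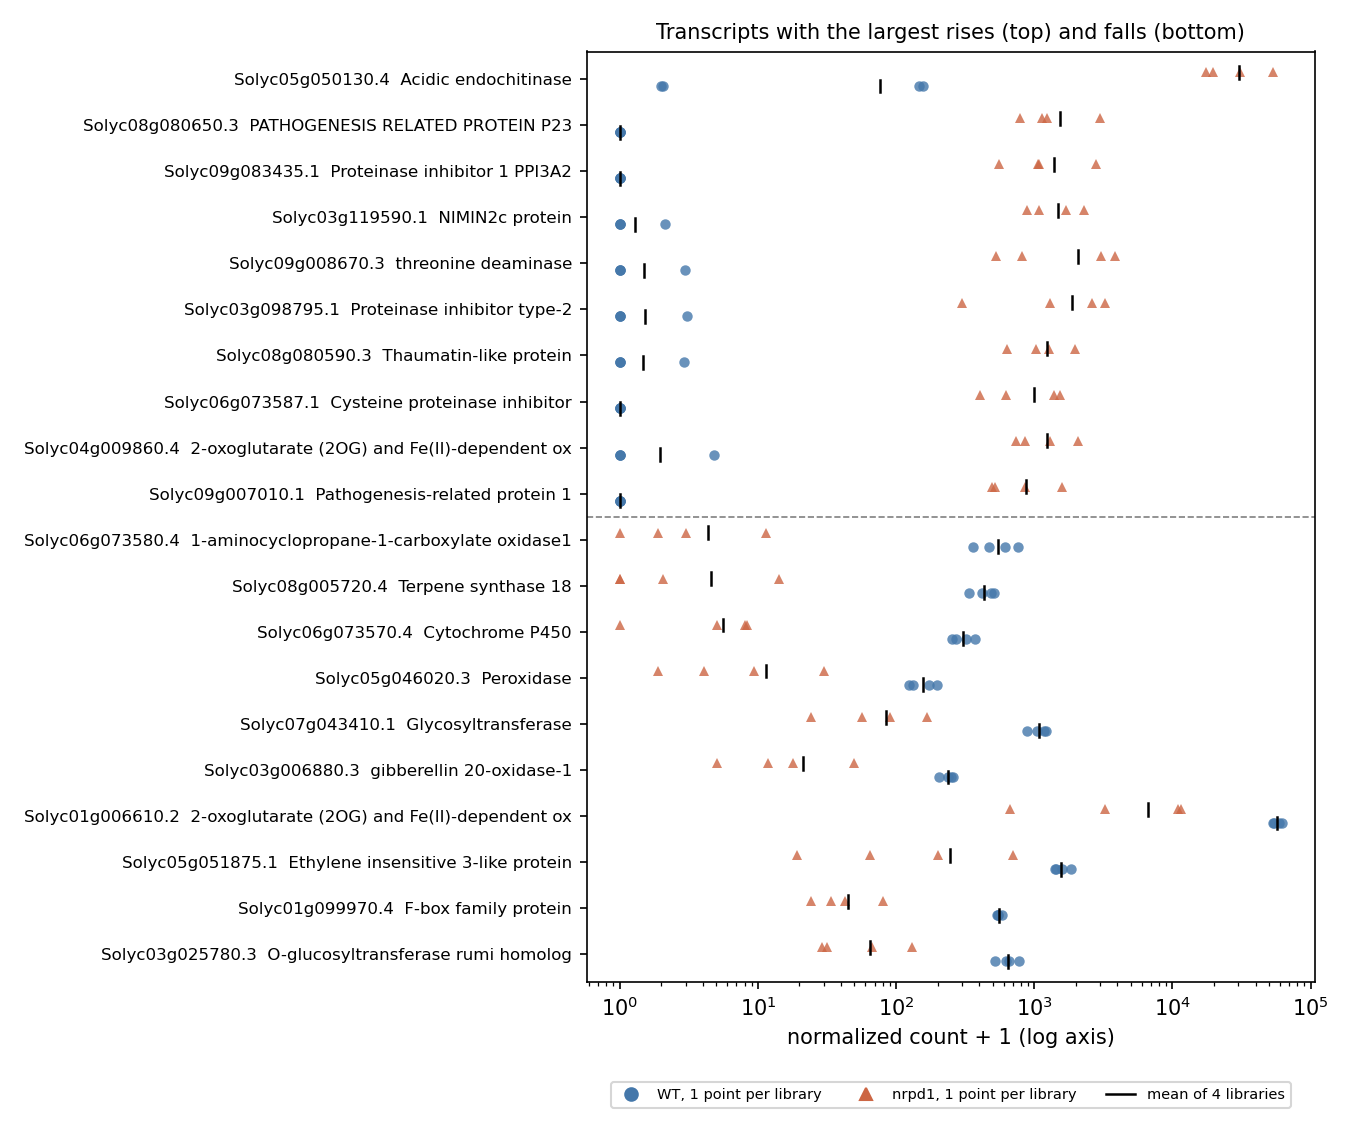
Normalized counts + 1 on a log axis of the 10 transcripts with the largest rises (above the dashed line) and the 10 with the largest falls, with WT libraries as circles, nrpd1 libraries as triangles and group means as black bars. No overlap between the values of the groups was a condition of the choice. Pathogenesis related protein P23 lies at 0 reads in all 4 WT libraries.

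Of 22705 genes tested with limma, 11277 passed an adjusted p of 0.05, 6563 higher and 4714 lower in nrpd1. At least 2-fold changes were found for 5412 genes, 4298 higher and 1114 lower. For 46.1% of the tested genes the values of the groups did not overlap, against 2.86% by chance. The authors' deposited comparison lists 6776 genes higher and 4555 lower at an adjusted p under 0.05, and 10913 genes were called by both, in the same direction. The higher share of the calls was 58.2%, against 53.7% with TMM, 55.7% with upper-quartile scaling and 68.8% with scaling to library totals, which moved the median log2 change of all tested genes from 0.04 to 0.15. Without WT 1 and WT 4 the numbers were 4991 higher and 2678 lower, and without WT 2 alone or WT 3 alone 5799 and 5821 higher and 3703 and 3697 lower.

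The share of genes that rose was largest among genes that WT embryos barely transcribed, where the choice of genes favours rises. Of 1354 tested genes with a WT mean under 1, 79.4% rose at least 2-fold and 0 fell by as much. A fall of that size cannot be reached there on the log2(normalized count + 1) scale. Genes silent in both groups do not enter the test, and each gene of this class needed reads in nrpd1 to enter. The direction in this class was therefore largely fixed in advance. Of 3112 genes with a WT mean of 1 to 10, 42.4% rose and 2.73% fell at least 2-fold. Among 9764 genes with a WT mean of 100 to 1000, 5.57% rose and 4.84% fell, and among 3512 genes at 1000 to 10000, 1.79% rose and 4.78% fell. A nrpd1 library held reads for 23580 ± 409 genes and a WT library for 21650 ± 120 (two-sided exact permutation test, p = 0.0286, the smallest that 4 against 4 libraries can give). After thinning to 20 M reads the numbers were 23322 ± 381 and 21274 ± 98.1 (two-sided exact permutation test, p = 0.0286).

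**Figure D2:**
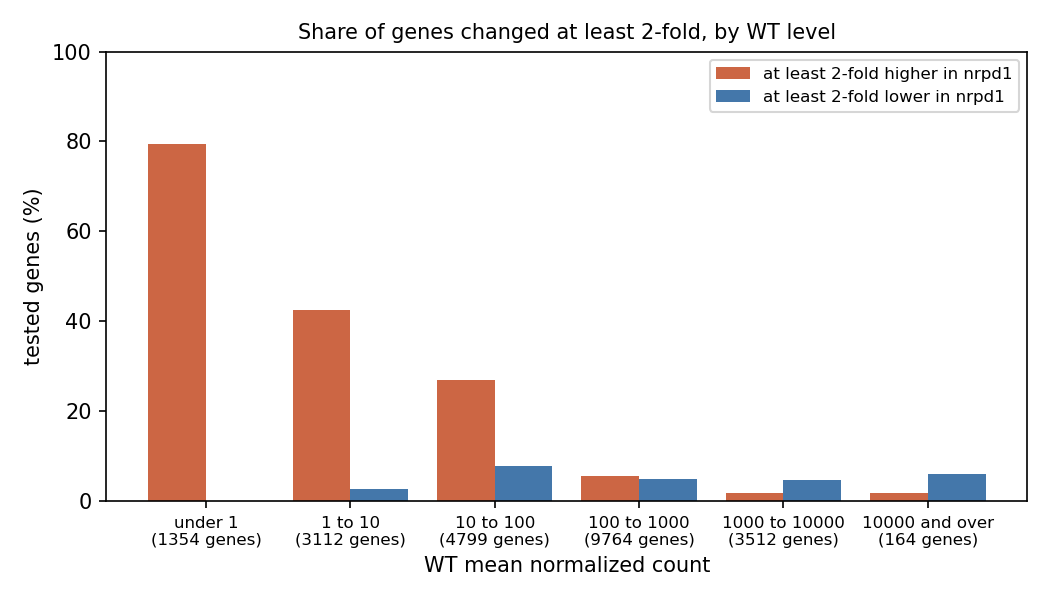
Share of tested genes, in percent, that were at least 2-fold higher or lower in nrpd1 with an adjusted p under 0.05, by WT mean normalized count. The share of rises goes from 79.4% under 1 to 1.83% at 10000 and over. In the class under 1 a fall of at least 2-fold cannot be reached, so only rises could be called there.

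The 6 transcripts with the highest WT mean were described as alcohol dehydrogenase-2 and 5 seed storage proteins. They took 44.2% ± 0.477 of the reads in WT and 39.7% ± 0.908 in nrpd1 (two-sided exact permutation test, p = 0.0286). The choice by WT level alone favours a higher share in WT. Among the storage proteins, the nitrogen reserve of the seed, 3 of 19 tested members rose and 8 fell, with the same numbers adjusted over the list alone. The list as a whole did not pass its test (camera adjusted p = 0.172; adjusted p = 0.308 with an estimated correlation). 11S globulin seed storage protein 2 (Solyc09g072560.4) fell from 3240200 ± 88999 to 2337400 ± 215410 (limma adjusted p = 0.000696), and a seed storage protein (Solyc03g005580.2) fell from 2121800 ± 59038 to 1391600 ± 148750 (limma adjusted p = 0.00017). The other storage proteins among the 6, given by abundance after their values were seen, did not pass, namely 2S albumin (Solyc08g080490.3, 3.96% of reads in WT and 5.04% in nrpd1, limma adjusted p = 0.0968), vicilin (Solyc09g082340.2, 5.10% and 4.87%, adjusted p = 0.106) and a seed storage protein (Solyc09g090150.4, 6.45% and 6.59%, adjusted p = 0.386). Vicilin-like antimicrobial peptides 2-1 (Solyc09g065470.3) rose from 67382 ± 1690 to 123690 ± 35017 (limma adjusted p = 0.00259). Of 22 oleosins and other oil body proteins 10 rose and 5 fell, 10 and 6 adjusted over the list alone (camera adjusted p = 0.754; adjusted p = 0.965 with an estimated correlation). Caleosin (Solyc01g005410.4), with 2 WT reads, had a ratio of 264.3 and a 95% counting interval of 72.8 to 2188.

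Of 52 tested late embryogenesis abundant proteins and dehydrins, which accumulate as seeds dry, 35 rose, 2 fell and 15 did not pass, with the same numbers adjusted over the list alone and a median log2 change of 0.93 (camera adjusted p = 2.78e-05; adjusted p = 0.287 with an estimated correlation). A late embryogenesis-like protein (Solyc01g095150.3) rose from 61.0 ± 7.49 to 2068 ± 817 and an 18 kDa seed maturation protein-like transcript (Solyc03g058330.3) from 491.7 ± 101 to 2197 ± 348. Of 68 genes of abscisic acid and gibberellin metabolism and signalling 34 rose and 10 fell, 36 and 10 adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.181 with an estimated correlation). A gibberellin receptor (Solyc09g074270.3) rose from 336 ± 72.0 to 2259 ± 477, and gibberellin 2-oxidase 4 (Solyc07g061720.3), of a family that inactivates gibberellins, from 2.86 ± 1.37 to 165 ± 95.6. Embryo and maturation regulators were split, with 7 of 24 higher and 7 lower, the same numbers adjusted over the list alone (camera adjusted p = 0.962; adjusted p = 0.965 with an estimated correlation). ABSCISIC ACID-INSENSITIVE 5-like protein 4 (Solyc09g009490.4) rose from 392 ± 35.1 to 1059 ± 226, and ethylene-responsive transcription factor ABI4 (Solyc03g095977.1) fell from 1221 ± 10.7 to 753 ± 115.

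Among genes of DNA replication and cell division more fell than rose. Of 79 core histone and DNA replication genes 43 fell and 7 rose, 44 and 7 adjusted over the list alone, with a median log2 change of -0.35 (camera adjusted p = 5.93e-08; adjusted p = 0.271 with an estimated correlation). Histone H4 (Solyc11g072860.2) fell from 2231 ± 162 to 845 ± 80.5 and histone H3 (Solyc10g008910.1) from 3491 ± 324 to 1581 ± 221, and reads of such near-identical copies may be split between genes. Of 145 cyclins and mitotic genes 67 fell and 25 rose, 69 and 25 adjusted over the list alone (camera adjusted p = 5.2e-05; adjusted p = 0.181 with an estimated correlation). Cyclin A1 (Solyc11g005090.2) fell from 1288 ± 44 to 483 ± 116, whereas D-type cyclin-3 (Solyc04g078470.3) rose from 377 ± 30.3 to 1527 ± 369. Of 202 cytosolic ribosomal protein genes 48 fell and 32 rose, 43 and 30 adjusted over the list alone, with a median log2 change of -0.10 (camera adjusted p = 0.0124; adjusted p = 0.718 with an estimated correlation). The ribosomal call was lost in 9 of 31 alternatives, with a range of 0.000139 to 0.718 over the alternatives in camera. Among them were leaving out nrpd1 1 (adjusted p = 0.093) or nrpd1 2 (adjusted p = 0.0517), scaling to library totals (adjusted p = 0.115) and fry (adjusted p = 0.343). 60S ribosomal protein L4 (Solyc09g007250.4) fell from 13644 ± 383 to 9456 ± 689, and 40S ribosomal protein S9 (Solyc01g010580.3) rose from 4039 ± 205 to 5943 ± 405.

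Of 343 tested defence and pathogenesis-related genes 141 rose, 45 fell and 157 did not pass, 142 and 46 adjusted over the list alone (camera adjusted p = 0.00964; adjusted p = 0.137 with an estimated correlation). Of 141 ethylene genes 58 rose and 20 fell, 58 and 21 adjusted over the list alone (camera adjusted p = 0.0106; adjusted p = 0.137 with an estimated correlation). The ethylene call was also lost without nrpd1 1 (adjusted p = 0.0717), nrpd1 2 (adjusted p = 0.0652) or nrpd1 4 (adjusted p = 0.0577) when the filter on low values was applied again. Ethylene-responsive transcription factor 4 (Solyc02g077810.1) rose from 3.34 ± 2.02 to 910 ± 135. Of 160 cell wall remodelling enzymes 72 rose and 25 fell, 73 and 28 adjusted over the list alone (camera adjusted p = 0.00801; adjusted p = 0.137 with an estimated correlation). A xyloglucan endotransglucosylase/hydrolase (Solyc05g005680.3), which cuts and rejoins wall polymers, rose from 2.59 ± 1.84 to 340 ± 116. Auxin transport and response genes, with 57 of 152 higher and 21 lower and 58 and 21 adjusted over the list alone, did not pass (camera adjusted p = 0.06; adjusted p = 0.137 with an estimated correlation) but passed in 12 of 31 alternatives, among them edgeR with TMM (adjusted p = 0.0133), with a range of 0.0058 to 0.137 in camera and a value of 1.14e-06 in fry, which tests against no change. Indole-3-acetic acid-amido synthetase 3-3 (Solyc02g064830.4), without a read in WT, was at least 320.0-fold higher in nrpd1, at 247 ± 140. Of 179 heat shock proteins and chaperones 45 rose and 34 fell, 44 and 32 adjusted over the list alone, with a median log2 change of 0.04, a mean of 0.37 and a test direction downward (camera adjusted p = 0.929; adjusted p = 0.965 with an estimated correlation). BAG family molecular chaperone regulator 1 (Solyc03g026220.3) rose from 68.8 ± 23.1 to 641 ± 165.

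Among markers of seed and fruit tissues outside the embryo single members rose, while the fruit and seed coat lists did not pass and the endosperm list was too short to test. Of 28 fruit flesh and ripening markers 14 rose and 6 fell, 15 and 6 adjusted over the list alone (camera adjusted p = 0.0857; adjusted p = 0.309 with an estimated correlation). The fruit list passed with no filter on low values (adjusted p = 0.0468) and with fry (adjusted p = 0.0001), with a range of 0.0468 to 0.309 over the alternatives in camera, and 1-aminocyclopropane-1-carboxylate oxidase 1 (Solyc07g049530.3), also a member of the ethylene list, rose from 8.75 ± 1.92 to 960 ± 481. Of 14 seed coat markers 4 rose and 2 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.673; adjusted p = 0.718 with an estimated correlation). Chalcone synthase 1 (Solyc09g091510.3), the entry enzyme of flavonoid synthesis, had levels of 2.61 ± 2.51 and 79.7 ± 105, with nrpd1 3 at 237 and the other nrpd1 libraries at 22.4 to 31.3. The endosperm list held 1 tested gene, agamous-like MADS-box protein AGL62 (Solyc10g012380.2), with 1 WT read, a level of 39.5 ± 21.1 in nrpd1, a ratio of 156.2 and a 95% counting interval of 27.7 to 6208. Of 40 MADS-box factors, among them regulators of flower, fruit and endosperm, 19 rose and 4 fell, with the same numbers adjusted over the list alone and a median log2 change of 1.19 (camera adjusted p = 0.0267; adjusted p = 0.181 with an estimated correlation). A MADS-box transcription factor (Solyc09g061950.1) without a WT read was at least 54.3-fold higher. The MADS-box call was lost in 14 of 31 alternatives, with a range of 0.016 to 0.798 over the alternatives in camera. Among them were leaving out nrpd1 2 (adjusted p = 0.0517) or nrpd1 4 (adjusted p = 0.0721), no filter on low values (adjusted p = 0.0839) and edgeR with TMM (adjusted p = 0.0896).

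Of 74 genes of the photosynthetic light reactions and Rubisco 32 rose and 10 fell, 34 and 10 adjusted over the list alone, with a median log2 change of 0.72 (camera adjusted p = 0.0267; adjusted p = 0.507 with an estimated correlation). Photosystem II 10 kDa polypeptide (Solyc07g066310.3) rose from 28.7 ± 9.96 to 238 ± 71.6, and a chlorophyll a-b binding protein (Solyc10g007690.3) from 33.5 ± 0.957 to 145 ± 42.3. The call of this list was lost in 7 of 31 alternatives, with a range of 0.0154 to 0.507 over the alternatives in camera. Among them were leaving out nrpd1 2 (adjusted p = 0.0608), edgeR with TMM (adjusted p = 0.079) and scaling to library totals (adjusted p = 0.0731). The call held in edgeR without a count filter and with a 1 CPM filter. Of 124 lipid biosynthesis genes 31 rose and 45 fell, 32 and 46 adjusted over the list alone, with a median log2 change of -0.12, a mean of 0.35 and a test direction downward (camera adjusted p = 0.113; adjusted p = 0.507 with an estimated correlation). A 3-ketoacyl-CoA synthase (Solyc09g083050.3) rose from 69.8 ± 8.58 to 604 ± 242. Of 41 meristem and patterning regulators 15 rose and 10 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.719; adjusted p = 0.718 with an estimated correlation). Homeobox protein knotted-1-like 3 (Solyc12g010410.3), without a WT read, was at least 38.4-fold higher, and TOPLESS 3 (Solyc01g100050.3), a transcriptional co-repressor, fell from 2247 ± 77.1 to 1063 ± 155.

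**Figure D3:**
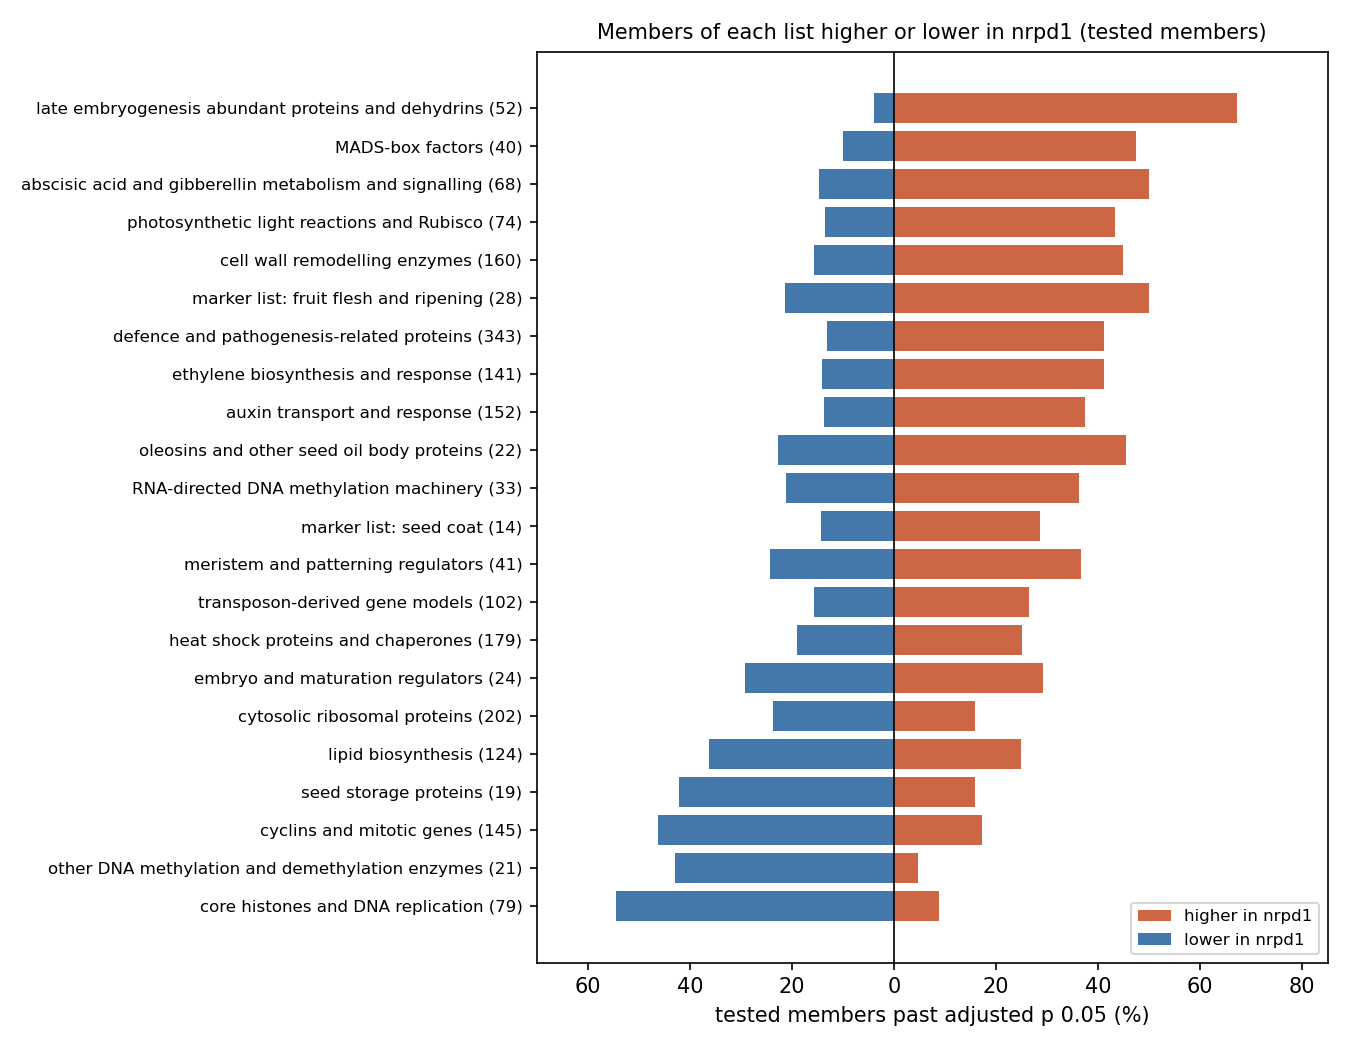
Percent of the tested members of each gene list that passed an adjusted p of 0.05 and were higher (right) or lower (left) in nrpd1, with the number of tested members in parentheses. Late embryogenesis abundant proteins lie at the top, with 35 of 52 members higher, and core histones and DNA replication at the bottom, with 43 of 79 lower.

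Within the RNA-directed DNA methylation machinery, the pathway NRPD1 belongs to, 12 of 33 tested genes rose and 7 fell, the same numbers adjusted over the list alone, and the list did not pass its test (camera adjusted p = 0.719; adjusted p = 0.718 with an estimated correlation). The largest rises were of genes with low WT levels. SNF2 domain-containing protein CLASSY 4-like (Solyc08g077570.3), of the family that recruits RNA polymerase IV to chromatin, rose from 18.1 ± 5.62 to 201 ± 91.3 (limma adjusted p = 1.83e-05), and a Dicer-like 3 gene (Solyc07g049150.2) rose from 11.4 ± 3.44 to 84.7 ± 24.9 (limma adjusted p = 4.22e-05). Other CLASSY 4 and CLASSY 4-like genes rose as well, from 17.96 to 106 (Solyc03g098175.1), from 2.84 to 28.2 (Solyc08g074710.1) and from 8.04 to 46.9 (Solyc08g077670.3). The call of another (Solyc08g061410.3, limma adjusted p = 0.0433) was lost in 17 of 25 alternatives, with a range of 0.0181 to 0.185. CLASSY 4-like genes with few reads did not pass (Solyc08g061390.3, limma adjusted p = 0.129; Solyc08g077640.3, adjusted p = 0.193; Solyc08g077650.1, adjusted p = 0.399). The more abundant Dicer-like 3 gene (Solyc08g067210.3) had levels of 801 ± 22.1 and 768 ± 72.7 (limma adjusted p = 0.563). CLASSY 1 (Solyc06g050510.3) rose from 8519 ± 532 to 11539 ± 1169 (limma adjusted p = 0.00163). A DNA-directed RNA polymerase subunit (Solyc01g096390.4) fell from 5584 ± 179 to 3844 ± 594 (limma adjusted p = 0.000753), and protein DEFECTIVE IN MERISTEM SILENCING 3 (Solyc03g083210.3) fell from 2318 ± 21.7 to 1527 ± 164 (limma adjusted p = 0.000139). Of the other genes with this description, Solyc06g051990.4 fell from 2070 to 1496 (limma adjusted p = 0.00318) and Solyc03g083170.3 from 77.9 to 40.6 (adjusted p = 0.0238; 0.0063 to 0.177 over the alternatives), Solyc03g083130.3 rose from 1.78 to 12.9 (adjusted p = 0.0052; 0.000874 to 0.0662), and Solyc03g071790.1 did not pass (adjusted p = 0.792). The DNA methyltransferase DRM2 genes had levels of 1260 ± 109 and 1113 ± 211 (Solyc05g053260.3, limma adjusted p = 0.224) and of 190 ± 43.5 and 264 ± 89.5 (Solyc05g053270.1, limma adjusted p = 0.113). Cytosine-5 DNA methyltransferase5 (Solyc02g062740.3), listed beforehand as DRM5, fell from 515 ± 22.1 to 378 ± 77.8 (limma adjusted p = 0.0162, 0.00781 to 0.0786 over the alternatives). DNA-directed RNA polymerase V subunit 5A (Solyc01g098320.4) fell from 2243 to 1728 (limma adjusted p = 0.041), a call lost in 22 of 29 alternatives. The remaining members of the list that were tested are not described singly.

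Of 21 other DNA methylation and demethylation enzymes 9 fell, 1 rose and 11 did not pass, with 9 lower and 2 higher adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.401 with an estimated correlation). DNA demethylase 2 (Solyc10g083630.2) fell from 3479 ± 167 to 1090 ± 242 (log2 change -1.70, SE 0.14, limma adjusted p = 3.23e-06). DNA demethylase 4 (Solyc03g123440.3) fell from 626 ± 39.1 to 377 ± 61.2 and DNA demethylase1 (Solyc09g009080.4) from 3343 ± 221 to 2427 ± 139; such enzymes remove methylated cytosine. The member that rose was cytosine-5 DNA methyltransferaseL1 (Solyc10g078190.2), from 890 ± 92.8 to 1430 ± 132.

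The second table asks which transposable elements, the main targets of RNA-directed DNA methylation, differ in transcript level. Most listed elements were more transcribed in nrpd1, and several Copia retrotransposons without a WT read reached high levels. The authors' table lists 673 elements on the SL4.0 genome, 611 of them (90.8%) higher and 62 lower, and holds only elements selected on these same samples, so the count is not independent evidence of the direction. They fall on 179 counted regions, 160 higher and 19 lower in nrpd1, and all 179 passed limma's test over the regions at an adjusted p of 0.05. These passes were largely fixed in advance by the selection. The adjusted p-values of single regions, taken over the selected regions alone, are no independent support either. Copia regions on chromosome 6 at 32519885 to 32524857 and on chromosome 2 at 36191674 to 36197170 had no WT read, and stood at 5611 ± 2545 and 4998 ± 1610 in nrpd1, at least 7255-fold and 6479-fold higher. No WT read was found in 47 of the regions.

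Gypsy and Copia retrotransposons made up most of the list. Of 354 Gypsy elements 324 were higher and 30 lower, and of 156 Copia elements 133 were higher and 23 lower. By counted regions, which several elements can share, Gypsy elements lay on 103 regions, 89 higher and 14 lower, and Copia elements on 69, 60 higher and 9 lower. The Harbinger, LINE and MuDR elements listed lay on 7, 12 and 13 regions, all higher. The largest level was that of a region on chromosome 5 at 6277457 to 6282634, which holds Gypsy and DNA elements, at 3119 ± 657 in WT and 7266 ± 1028 in nrpd1 (limma adjusted p = 3.52e-05). The largest fall was on chromosome 12 at 38106943 to 38112299, with Copia and Gypsy elements, from 173 ± 81.1 to 1.59 ± 1.5 (limma adjusted p = 6.16e-07). With library sizes taken from the element table itself, 88 regions were higher and 34 lower, and with an adjusted p under 0.01 and an absolute log2 of at least 2 in the authors' values 126 regions were higher and 6 lower. Neither table tells the strand of the reads, so read-through from genes into elements was not separated. In the gene table, 27 of 102 transposon-derived gene models rose and 16 fell, 25 and 15 adjusted over the list alone (camera adjusted p = 0.929; adjusted p = 0.965 with an estimated correlation). A Harbinger transposase-derived nuclease (Solyc07g040960.1) rose from 5.72 ± 2.48 to 511 ± 274.

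**Figure D4:**
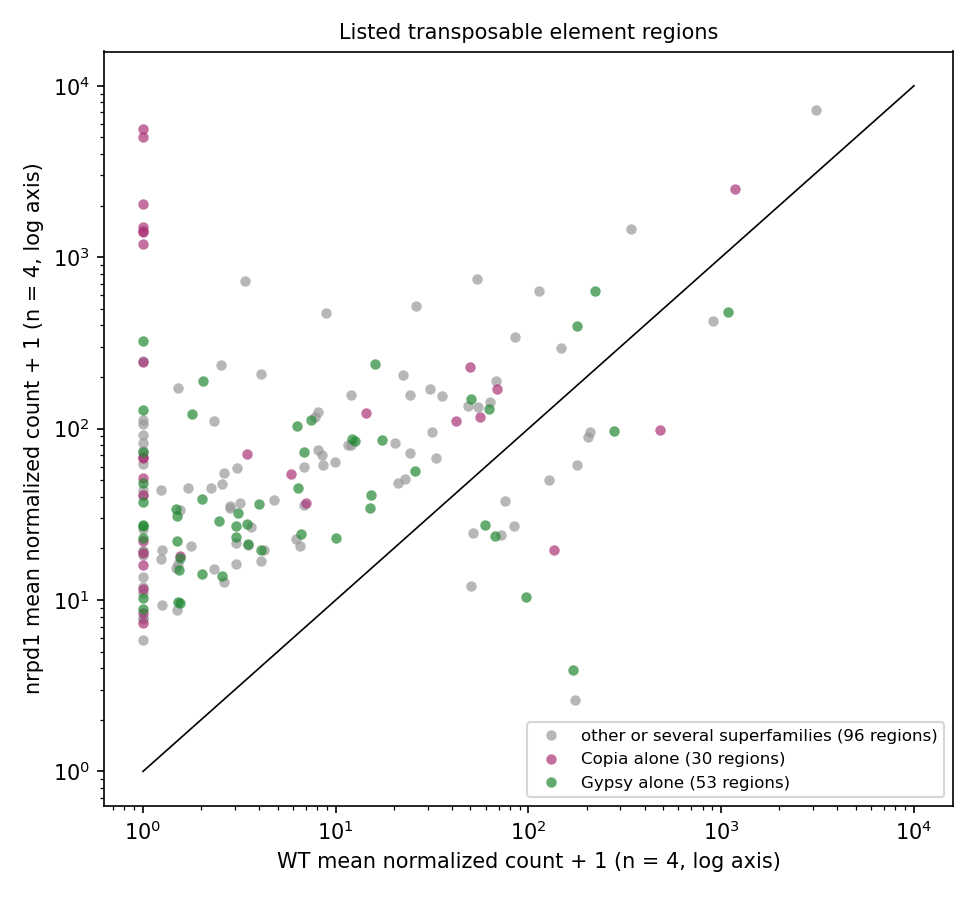
Mean normalized counts + 1 over 4 libraries in WT (x axis) and nrpd1 (y axis), both on log axes, of the 179 counted regions of listed transposable elements, with a line of equal levels. Of the regions 160 lie above the line and 19 below it, and those at the left edge had no read in WT.

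The libraries separated by genotype. The first principal component held 76.9% of the variance and parted WT from nrpd1. Pearson's correlation of log2 levels across genes, which are not independent replicates, was 0.979 to 0.985 among WT libraries, 0.945 to 0.965 among nrpd1 libraries and 0.835 to 0.903 between the groups. The nrpd1 libraries differed in the size of the changes: over the 5412 genes changed at least 2-fold, the slope of each library on the mean of the other nrpd1 libraries was 1.08, 0.901, 1.16 and 0.813 in nrpd1 1 to nrpd1 4.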

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

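The tests on traces in WT 1 and WT 4 were chosen only after the result was seen, and their form was changed after results of earlier forms had been seen: a first choice of transcripts, whose values are not used here, and for carry-over the dispersion around a mixture of nrpd1 libraries, which was 10.9, 8.23, 6.86 and 7.56 in WT 1 to WT 4 and decided nothing.

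WT 1 and WT 4 held traces of transcripts that are high in nrpd1, such as acidic endochitinase (Solyc05g050130.4) at 146 and 156 normalized counts against 0.982 and 1.05 in WT 2 and WT 3. Over 70 transcripts with an nrpd1 mean of at least 500 and a WT mean of at most 1% of it, WT 1 to WT 4 held 936, 220, 196 and 607 reads, or 0.634%, 0.153%, 0.145% and 0.48% of the nrpd1 level. Reads carried over from nrpd1 libraries are argued against as the source of the whole excess over WT 2 and WT 3: 14 of the transcripts had no read in WT 1 and 19 in WT 4, against at most 2.74 and 7.82 expected, with upper counting limits of 8 and 16, if the excess came from any of the nrpd1 libraries, and a smaller share carried over stays open. A low-level induction shared by WT 1 and WT 4 may be a cause: their reads went together over transcripts given the nrpd1 libraries (partial Spearman rho 0.438, one-sided permutation test, p = 0.00011), but WT 2 and WT 3 had a rho of 0.656, which keeps this open. No biological explanation that the groups name was tested.

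The size of the changes differed between the nrpd1 libraries, with slopes of 1.08, 0.901, 1.16 and 0.813 in nrpd1 1 to nrpd1 4. Library depth is argued against, as the range of the slopes after thinning to 20 M reads was 98.1% of that before. WT-like RNA mixed into nrpd1 2 and nrpd1 4 could lower the rises, and shares of 31.3% and 44.3% would be needed. Of 1114 lowered genes, 8.98% in nrpd1 2 and 24.2% in nrpd1 4 lay below the level such a mixture would leave. The shares rest on an assumed reference, the mean of the other nrpd1 libraries, so over all lowered genes the mixture cannot be told apart. Among the largest falls, terpene synthase 18 (Solyc08g005720.4) stood at 13.3 and 1.04 in nrpd1 2 and nrpd1 4, against 435 in WT. 1-aminocyclopropane-1-carboxylate oxidase1 (Solyc06g073580.4) stood at 0.888 and 10.4, against 548. For these transcripts the values argue against mixtures of the full shares, and a smaller share stays open. The groups name no biological difference between the nrpd1 libraries, and no biological explanation was tested.

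At least 2-fold rises outnumbered falls, 4298 against 1114. The excess lay in genes low in WT. By WT mean, rises and falls were 1075 and 0 under 1, 1320 and 85 at 1 to 10, and 1293 and 378 at 10 to 100. They were 544 and 473 at 100 to 1000, 63 and 168 at 1000 to 10000, and 3 and 10 above. In the class under 1 the filter and the scale largely fixed the direction in advance, which the tests of scaling and depth below do not address. Scaling of the libraries is argued against, with 3.35 rises per fall as the smallest number over 3 other scalings, and so is depth, with 3.82 after thinning. RNA of other seed or fruit tissue in the nrpd1 samples could raise silent genes: of 17 marker genes under 10 in WT 58.8% rose, against 53.6% of other such genes (two-sided Fisher's exact test across genes, which are not independent replicates, p = 0.809), too few to decide. WT embryos held 26 of the 43 tested marker genes at 10 or more, and the most abundant, a ripening regulated protein (Solyc05g008600.3), went from 19508 to 14562. Other fruit markers rose, and over the fruit list 14 rose and 6 fell. 1-aminocyclopropane-1-carboxylic acid synthase-2 (Solyc01g095080.3) rose from 12.4 to 288 and ripening regulated protein DDTFR10/A (Solyc05g052040.1) from 2.71 to 328. An oxygenase of the fruit list (Solyc09g089580.4), with 3 WT reads, stood at 593 in nrpd1. The loss of NRPD1 itself stays open and was not tested apart from these.

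In 25 of 305 groups of 4 libraries, where chance gives 5% or about 15, a library stood far from the other 3; 11 of these held reads in 1 library alone, which always stands apart, so the chance rate does not apply to them and the number says little. In WT 1 these were histone H3 (Solyc01g086820.4) at 2297, DNA-directed RNA polymerase V subunit 5A (Solyc01g098320.4) at 2379, histone H4 (Solyc11g072860.2) at 2473, hydroxysteroid dehydrogenase (Solyc06g072670.3) at 21270 and gibberellin receptor (Solyc09g074270.3) at 443, all above the others. Also in WT 1, with 0 in the others, were a 2-oxoglutarate and Fe(II)-dependent oxygenase (Solyc04g009860.4) at 3.84, a phosphatidyltransferase (Solyc05g006390.1) at 0.96 and thaumatin-like protein (Solyc08g080590.3) at 1.92. In WT 2, dihydroflavonol 4-reductase (Solyc03g031470.3) and CLASSY 4-like (Solyc08g077650.1) stood at 2.95 each and threonine deaminase (Solyc09g008670.3) at 1.96, with 0 in the others, and 1-aminocyclopropane-1-carboxylate oxidase 1 (Solyc07g049530.3) was lower at 5.89. In WT 3, proteinase inhibitor type-2 (Solyc03g098795.1) stood at 2.09 and a xyloglucan endotransglucosylase/hydrolase (Solyc05g046290.3) at 1.05, with 0 in the others, and a SAWADEE HOMEODOMAIN protein (Solyc11g070160.2) was lower at 125. In WT 4, NIMIN2c protein (Solyc03g119590.1) and AGL62 (Solyc10g012380.2) stood at 1.12 each, with 0 in the others, and an oxygenase of the fruit marker list (Solyc09g089580.4) at 0.

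Among the nrpd1 libraries, nrpd1 1 was lower for histone H3 (Solyc10g008910.1) at 1251 and 60S ribosomal protein L18a-like protein (Solyc07g061970.3) at 451. In nrpd1 3, chalcone synthase 1 (Solyc09g091510.3) was higher at 237, Dicer-like protein 3 (Solyc08g066063.1) stood at 4.5 with 0 in the others, and the mean log2 level of the seed coat markers was higher at 6.19. In nrpd1 4, a DRM2 gene (Solyc05g053270.1) was higher at 397 and the mean log2 level of the RNA-directed DNA methylation list was lower at 6.66.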

How the results depend on the processing

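Tests chosen only after the result was seen are edgeR with TMM, the limma scalings, leaving out WT 1 and WT 4 together, edgeR for the elements and the filter applied again when a library is left out. Leaving out a library first applied the filter again, which dropped genes silent in WT, and after that result was seen the same genes were refitted; both are given.

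Of 36 alternatives, each one run on genes gave more rises than falls. Leaving out each library gave 9502 to 12127 genes, 4935 to 5839 of them at least 2-fold, 8 to 12 lists and 174 to 178 element regions, and with the filter applied again 9244 to 11349 genes, 4253 to 5163 at least 2-fold and 7 to 12 lists (7 without nrpd1 2, a move from 11 by over 1.5 times). The element regions were selected on all the libraries, so their numbers say little about stability. Other counts that moved by over 1.5 times were lower genes at an adjusted p under 0.01 (2961, a stricter limit) and without WT 1 and WT 4 (2678, fewer samples; higher genes 4991), at least 2-fold genes in edgeR with a 1 CPM filter (3150, of them 2403 higher, fewer genes tested), and element regions with sizes from the element table (88 higher, 34 lower, since most listed elements rise) or with stricter limits on the authors' values (6 lower). With camera's estimated correlation 0 lists passed (5 at an unadjusted p under 0.05), and with fry 18; fry tests another hypothesis. Of the 11 lists 7 passed in every alternative but the estimated correlation. The replicate numbers pair nothing that the labels state: deviations of equal numbers correlated at -0.010, 0.033, -0.009 and -0.099 and no WT library went best with its own number. The block gave 10554 genes, 5310 at least 2-fold, 11 lists and 179 regions, and ended the calls of an ethylene insensitive 3-like protein (Solyc05g051875.1, adjusted p = 0.0625) and a CLASSY 4-like gene (Solyc08g061410.3, adjusted p = 0.0601). Of 119 called named genes 7 lost the call in some of 29 alternatives and 0 reversed in limma, edgeR or DESeq2 (3 of all 133 named genes did). Alternatives on the transcript of the mutated gene and on genes near elements were not run.

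Directions that reversed were of results not past the test, and the cause was not tested. Leaving out a library, the list's adjusted p ranged from 0.86 to 0.992 for embryo regulators, 0.82 to 0.983 for transposon-derived models and 0.659 to 0.956 for heat shock proteins, and the log2 change from -0.37 to 1.002 for DEFECTIVE IN MERISTEM SILENCING 3 (Solyc03g071790.1) and -0.033 to 0.17 for a SAWADEE HOMEODOMAIN protein (Solyc11g070160.2). With the filter applied again, adjusted p values were 0.977 (embryo regulators, without WT 2), 0.9748 (transposon-derived, WT 4), 0.945, 0.998 and 0.77 (oleosins, meristem, transposon-derived, nrpd1 1), 0.813 (heat shock and transposon-derived, nrpd1 2), 0.998 and 0.727 (the same, nrpd1 3), 0.99 (oleosins and meristem, nrpd1 4) and 0.834 (heat shock and transposon-derived, nrpd1 4); the log2 change of Solyc03g071790.1 was -0.23 (WT 4), -0.37 (nrpd1 1) and -0.0040 (nrpd1 2) and that of Solyc11g070160.2 -0.033 (nrpd1 1). Embryo regulators also reversed with no filter (0.95) and in edgeR without a count filter (0.982), and heat shock proteins with fry (0.0509) and the 1 CPM filter (0.926). Transposon-derived models and seed coat markers reversed in edgeR with TMM (0.731, 0.83), RLE (0.701, 0.819), upper quartile (0.719, 0.833) and 1 CPM (0.70, 0.754), and transposon-derived models with library totals (0.886) and without WT 1 and WT 4 (0.902). A Dicer-like 3 gene (Solyc08g067210.3) had a log2 change of 0.041 with library totals. Depth limits calls of genes with few reads: 3 reads stand for 0.0952 to 0.11 CPM.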

Other observations

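The tests on gene families were chosen only after the data had been seen.

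Of all families with at least 10 tested members 49 passed in camera, 29 up and 20 down, and with an estimated correlation 0 passed and 26 had an unadjusted p under 0.05, so the calls of the families below are lost with it. None of the 49 changed the sign of its median under the other scalings run. Of 56 WRKY transcription factors, regulators of immune responses, 40 rose and 0 fell in limma (median log2 change 1.85, camera adjusted p = 1.65e-09; adjusted p = 0.547 with an estimated correlation). All 14 calmodulin binding proteins rose, with a median of 4.33, as did 37 of 54 glutathione S-transferases, with 7 lower, 24 of 36 NAC domain-containing proteins, with 1 lower, 15 of 20 xyloglucan endotransglucosylase/hydrolases, with 1 lower, and 20 of 28 non-specific lipid-transfer proteins. Families with a downward call were pentatricopeptide repeat-containing proteins, which process RNA of organelles, with 125 of 276 lower and 6 higher (median -0.54, camera adjusted p = 1.07e-09; adjusted p = 0.547 with an estimated correlation), kinesins, with 28 of 49 lower and 7 higher, and structural maintenance of chromosomes proteins, with 8 of 10 lower. Families that did not pass include thaumatins, with 4 of 15 higher and 2 lower (camera adjusted p = 0.844), defensins, with 11 of 16 higher and 2 lower (adjusted p = 0.0531), and ethylene-responsive transcription factors, with 28 of 61 higher and 8 lower (adjusted p = 0.061).

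Genes with consecutive identifiers changed together to a small degree, which may point to changes shared by chromosomal neighbours: Pearson's correlation across 21209 pairs of genes with different descriptions was 0.119 (0.175 over all pairs), and the highest of 1000 shuffles was 0.0255. Adjacent large falls were those of cytochrome P450 (Solyc06g073570.4) and 1-aminocyclopropane-1-carboxylate oxidase1 (Solyc06g073580.4), and of the serine/threonine-protein phosphatase 7 long form-like proteins (Solyc09g061633.1 and Solyc09g061637.1), the latter with a shared description, outside the tested pairs, and chosen after their values were seen. Beside the first pair, the next identifier, cysteine proteinase inhibitor (Solyc06g073587.1), rose at least 1297-fold.

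Release of transposon-derived gene models could add to the rises among genes near silence in WT. Of 45 such models under 10 in WT 42.2% rose at least 2-fold, against 53.7% of other such genes (two-sided Fisher's exact test across genes, p = 0.134), too few to decide.

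Over the 35 splits of the 8 libraries into groups of 4, the real split gave the most genes, 11277 against at most 1 in another split. It also gave the most genes changed at least 2-fold, 5412 against at most 1. A share of 1 in 35 is the smallest that these splits can give. Every other split puts both genotypes into each group, which widens the spread within groups. The splits therefore do not measure how many calls chance would give. Chance cannot be excluded for the number of lists (11; highest other 11; 2 splits as large). The count of element regions (179; highest other 0; 1 split) decides nothing, since the regions were selected on the real split.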
